A study of Mus musculus with 4 samples.

How the data were processed

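Nuclei from the kidney and the cerebral cortex of male C57BL/6J mice aged 8 weeks were profiled by droplet-based single-nucleus RNA sequencing with 5′-end chemistry (10x Genomics), in which each droplet barcode marks 1 nucleus and each unique molecular identifier (UMI) marks 1 captured RNA molecule. The kidney was cut radially and the brain sample was the cortical region, per the labels' protocols. There were 4 libraries, 1 for each tissue in wild-type and in α-klotho knockout mice. The labels do not say whether the kidney and the cortex of a genotype came from the same animal.

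The deposited data used here were 2 tables of nuclei, 1 per tissue, with a line for each nucleus that gives its barcode, its library, its UMI count, its number of detected genes and its cell type. The UMI count and the count of detected genes are whole numbers with no normalization, as deposited by the authors, under column names that are Seurat's defaults per the file headers. Cell type names are the authors' own annotation, per the file headers. Cell Ranger 7.0.0, Seurat 5.0.1 and the genome build GRCm38 are named in the submitters' processing notes, without a role or an order. The filters on nuclei, the treatment of doublets, the counting of intronic reads, the integration of libraries and the method of annotation are not given in the sources used here. In the deposited tables the lowest UMI count of a nucleus was 500 and the lowest number of detected genes was 206. Gene-level counts were not analysed here, so no gene's expression is reported and the loss of Klotho was not checked in the libraries. The tables name the libraries as control and Klotho knockout. The knockout names match the sample titles, and control was taken as the wild-type library because it is the only other sample of that tissue. The group and library names were identical in every line, with 0 exceptions, and 0 names belonged to no sample.

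For each tissue, the share of a library's nuclei in each annotated cell type was computed with its exact Clopper-Pearson 95% interval. The ratio of the knockout to the wild-type share was taken as the size of a difference. UMIs and detected genes per nucleus were summarised as medians with quartiles per library and per cell type, and as the ratio of the knockout to the wild-type median. A distribution-free 95% interval of each median, from binomial order statistics, was used where medians are set against each other. Each group holds 1 library, so there was no test, no p-value and no standard error. Intervals cover the counting of nuclei only and hold no variation between animals, dissections or library preparations. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

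Before the data were examined, it was fixed that every type with at least 1% of the nuclei of either library would be named, and that the proximal, distal convoluted and connecting tubules, choroid plexus or ependymal cells and immune cells would be named at any size. A type was to be described as holding a higher or lower share in the knockout library only if its ratio was at least 1.5 or at most the inverse of 1.5, the 2 exact intervals did not overlap and the type had at least 50 nuclei over both libraries. For depth, the 3 highest and 3 lowest ratios of median UMIs among types with at least 50 nuclei per library were to be named. The share rule was tested on simulated data, with nuclei drawn from the pooled composition of each tissue at the real library sizes. In 100 simulated kidney pairs with equal shares it called 1 of the 9 types in 1 pair, and in 100 simulated cortex pairs it called 0. A type whose share was simulated at 0.5 times its level was called in 98.9% of 89 kidney pairs and in 100% of 83 cortex pairs. Proximal tubule nuclei and neurons, the most abundant types, were never the changed type, so these rates do not cover them. For types that abundant the size rule asks for a large shift of the whole library. A type simulated at 2 times its share was called in 100% of both, but the kidney pairs then also gave 7 calls of unchanged types, because shares sum to a fixed total. These simulations cover counting error only.

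The alternatives fixed beforehand were a minimum of 500 detected genes, leaving out the 5% of nuclei with the most UMIs in each library, the UMI range that both libraries share, leaving out the most abundant type, shares of UMIs in place of nuclei, equal weight for each of 10 UMI deciles, broad classes of types, the mean of log10 values in place of the median, and libraries standardised to their mean composition. A minimum of 1000 UMIs was added after seeing the data. The broad classes joined the distal convoluted with the connecting tubule, the intercalated with the principal cells of the collecting duct, endothelial with mesangial cells, and astrocytes, oligodendrocytes and their precursors, and their make-up was set after the type names and counts were seen. Planned results on mitochondrial percentages, on scores and on gene values were not computed, since the tables used here give none. The position of the Klotho gene was taken from the GENCODE annotation given for this work, which annotates GRCm38.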

Results

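The series profiled single nuclei of the kidney and of the cerebral cortex in wild-type mice and in mice lacking α-klotho. Klotho is a membrane protein made mainly in the distal tubule of the kidney and in the choroid plexus of the brain, where it acts as the co-receptor for the phosphate-regulating hormone FGF23, and mice without it show features that resemble premature ageing. Its gene, Kl (ENSMUSG00000058488), lies on the forward strand of chromosome 5 from position 150952607 to 150993817 in GRCm38, with 1 protein-coding transcript of 5 exons. The kidney data held 9181 wild-type and 7879 knockout nuclei in 9 annotated cell types, and the cortex data held 12540 wild-type and 9344 knockout nuclei in 6 annotated cell types. The nuclei summed to 49219695 UMIs in the wild-type kidney library, 32773079 in the knockout kidney library, 79779640 in the wild-type cortex library and 74104270 in the knockout cortex library. No gene values were analysed here, so the deletion was not checked in the libraries. Each group was 1 library, so the differences below describe these libraries, have no replicate check and carry no test.

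The first comparison asks which cell types made up the kidney nuclei with and without Klotho. Endothelial, mesangial and connecting tubule nuclei each held a lower share in the knockout library, and podocytes held a higher share. These 4 of the 9 annotated types met the size and interval rule, 3 of them lower and 1 higher. The remaining 5 types, among them the proximal tubule and the loop of Henle, had ratios between 0.79 and 1.41.

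Endothelial cells, which line the blood vessels and the glomerular capillaries, made up 10.1% of wild-type kidney nuclei (927 nuclei, 95% exact binomial interval 9.49 to 10.7%) and 4.68% of knockout nuclei (369 nuclei, 4.23 to 5.17%), a ratio of 0.46. Mesangial cells, the contractile stromal cells that support the glomerular capillaries, made up 4.38% of wild-type nuclei (402 nuclei, 3.97 to 4.82%) and 2.21% of knockout nuclei (174 nuclei, 1.90 to 2.56%), a ratio of 0.50. Podocytes, the epithelial cells that wrap the same capillaries, differed in the other direction, with 0.99% of wild-type nuclei (91 nuclei, 0.80 to 1.22%) and 1.75% of knockout nuclei (138 nuclei, 1.47 to 2.07%), a ratio of 1.77. There were 10.2 endothelial nuclei per podocyte nucleus in the wild-type library (8.21 to 12.8) and 2.67 in the knockout library (2.19 to 3.28). The corresponding numbers for mesangial nuclei were 4.42 per podocyte nucleus (3.51 to 5.61) and 1.26 (1.00 to 1.59). The annotation does not say how many of the endothelial and mesangial nuclei came from glomeruli.

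In the distal nephron, where Klotho is most abundant and where calcium and sodium reabsorption are adjusted, the 2 neighbouring segments differed in opposite directions. Connecting tubule nuclei made up 3.29% of the wild-type library (302 nuclei, 2.93 to 3.67%) and 1.70% of the knockout library (134 nuclei, 1.43 to 2.01%), a ratio of 0.52. Distal convoluted tubule nuclei made up 5.77% of the wild-type library (530 nuclei, 5.30 to 6.27%) and 8.16% of the knockout library (643 nuclei, 7.57 to 8.79%). That ratio of 1.41 lay below the size rule of 1.5, although the intervals did not overlap. With proximal tubule nuclei left out, which raises the ratio of every other type, it was 1.51 and met the rule. It stayed below 1.5 under the other alternatives, at 1.25 with equally weighted UMI deciles and 1.33 by share of UMIs. Under the limits on genes and UMIs it was 1.40 to 1.44. There were 1.75 distal convoluted nuclei per connecting tubule nucleus in the wild-type library (1.52 to 2.03) and 4.80 in the knockout library (3.98 to 5.82). Summed, the 2 segments held 9.06% of wild-type nuclei (8.48 to 9.67%) and 9.86% of knockout nuclei (9.21 to 10.5%), a ratio of 1.09 with overlapping intervals.

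Proximal tubule nuclei, the segment that reclaims most filtered phosphate, glucose and amino acids and on which FGF23 acts, were the largest type in both libraries. They made up 54.3% of wild-type nuclei (53.3 to 55.3%) and 57.2% of knockout nuclei (56.1 to 58.3%), a ratio of 1.05. For a type this abundant the size rule asks for a large shift of the whole library, so the lack of a call says little. Loop of Henle nuclei made up 17.5% (16.7 to 18.3%) and 20.5% (19.6 to 21.4%), a ratio of 1.17. Both pairs of intervals were apart, but both ratios were below the size rule, and each lay on the other side of 1 under 1 alternative, at 0.99 for proximal tubule by share of UMIs and 0.93 for loop of Henle with UMI deciles weighted equally. Shares sum to a fixed total, and endothelial and mesangial nuclei together held 14.5% of wild-type and 6.89% of knockout nuclei. That gap alone raises the knockout shares of the other types, so ratios slightly above 1 need not mean more of those nuclei. In the collecting duct, intercalated cells, which handle acid and base, made up 2.37% (2.07 to 2.71%) of wild-type and 2.74% (2.39 to 3.13%) of knockout nuclei. Principal cells, which reabsorb water and sodium, made up 1.32% (1.09 to 1.57%) and 1.04% (0.83 to 1.29%), and for both collecting duct types the intervals overlapped. The kidney annotation has no name for immune cells or fibroblasts, so no share is given for them. The knockout kidney library was shallower, with a median of 3379 UMIs per nucleus against 4677, and the shares stand beside this gap in depth.

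**Figure D1:**
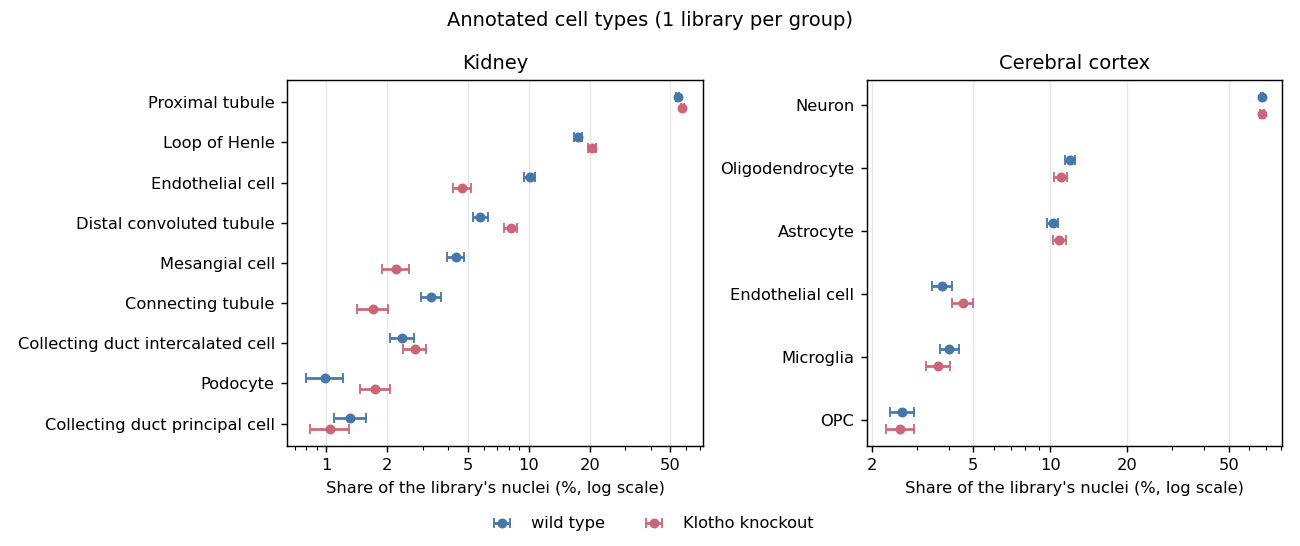
Share of each annotated cell type among the nuclei of the kidney libraries (left) and the cortex libraries (right), in percent on a log axis, for the wild-type library (blue) and the Klotho knockout library (red); points are shares and bars are 95% exact binomial intervals, which cover counting error only. In kidney the endothelial share was 10.1% in wild type and 4.68% in the knockout, and in cortex the neuron share was 67.4% in both libraries.

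The second comparison asks the same of the cerebral cortex. None of the 6 annotated types met the size and interval rule, and 0.90 to 1.20 was the range of the ratios of knockout to wild-type shares. Neurons made up 67.4% of the nuclei in the wild-type library (8448 nuclei, 66.5 to 68.2%) and 67.4% in the knockout library (6299 nuclei, 66.5 to 68.4%). From that wild-type share the size rule could not have called neurons higher, because the share needed exceeds the whole library. Only a large fall could have been called lower. The lack of a call for neurons thus says little, although the shares themselves were nearly equal. Excitatory and inhibitory neurons were not separated in the annotation. Oligodendrocytes, the myelinating glia, made up 12.0% (11.4 to 12.6%) of wild-type and 11.0% (10.4 to 11.6%) of knockout nuclei. Their precursors made up 2.62% (2.35 to 2.92%) and 2.59% (2.28 to 2.93%), and astrocytes 10.2% (9.71 to 10.8%) and 10.8% (10.2 to 11.5%). Microglia, the resident immune cells of the brain, made up 4.04% of wild-type nuclei (506 nuclei, 3.70 to 4.39%) and 3.64% of knockout nuclei (340 nuclei, 3.27 to 4.04%), a ratio of 0.90.

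Endothelial cells were the cortical type with the highest ratio, 1.20, at 3.77% of wild-type nuclei (473 nuclei, 3.45 to 4.12%) and 4.54% of knockout nuclei (424 nuclei, 4.12 to 4.98%). Their intervals were apart by a small margin and the ratio was below the size rule. The kidney ratio for endothelial cells was 0.46, and the difference between the tissues was not tested. The cortex annotation has no choroid plexus or ependymal type, the brain cells in which Klotho is most abundant. The part of a library's nuclei that would need another type name to make the shares of both libraries equal was 1.42 percentage points in cortex and 9.45 percentage points in kidney. These values depend on how finely each tissue's nuclei were named. Any shift among kinds of neuron would not count in cortex, so the tissues cannot be ranked by them. The knockout cortex library was the deeper of its pair, with a median of 6323 UMIs per nucleus against 4143.

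The third comparison concerns how much RNA was captured per nucleus. In kidney, the knockout library had fewer UMIs per nucleus in each of the 9 cell types, and in cortex it had more in each of the 6. Over all kidney nuclei the median was 4677 UMIs in wild type (quartiles 2654 and 7067) and 3379 in the knockout (2169 and 4596), a ratio of 0.72. The median number of detected genes was 2185 (1474 and 2881) in wild type and 1760 (1248 and 2202) in the knockout, a ratio of 0.81. Over all cortex nuclei the median was 4143 UMIs in wild type (1675 and 8502) and 6323 in the knockout (2076 and 10892), a ratio of 1.53. That is larger than in any single cortex type, where the ratios of medians ran from 1.07 to 1.30. The 2 library medians lay near the lower quartiles of neurons, 3608 in wild type and 6043 in the knockout, whose ratio was 1.68. The median number of detected genes there was 1875 (1000 and 2954) in wild type and 2542 (1213 and 3476) in the knockout, a ratio of 1.36.

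Among kidney types, the lowest ratios of median UMIs were in mesangial nuclei (0.56, from 3336 to 1885), proximal tubule nuclei (0.62, from 6343 to 3948) and distal convoluted tubule nuclei (0.67, from 4249 to 2831). The highest were in podocytes (0.86, from 3211 to 2755), connecting tubule nuclei (0.76, from 4085 to 3105) and loop of Henle nuclei (0.76, from 3070 to 2327). With means of log10 values the connecting tubule ratio was 0.73, below the proximal tubule ratio of 0.74. The intervals of the medians were apart in 8 of the 9 kidney types, podocytes being the exception. Among cortex types, the highest ratios were in neurons (1.30, from 7025 to 9146), microglia (1.20, from 1209 to 1445) and oligodendrocyte precursors (1.19, from 2834 to 3366). The lowest were in endothelial cells (1.07, from 1256 to 1340), oligodendrocytes (from 1777 to 1951) and astrocytes (1.18, from 2081 to 2452). The intervals of the medians were apart in 5 of the 6 cortex types, endothelial cells being the exception. With 1 library per group, genotype cannot be separated from dissection, nuclei isolation or sequencing as sources of these differences.

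**Figure D2:**
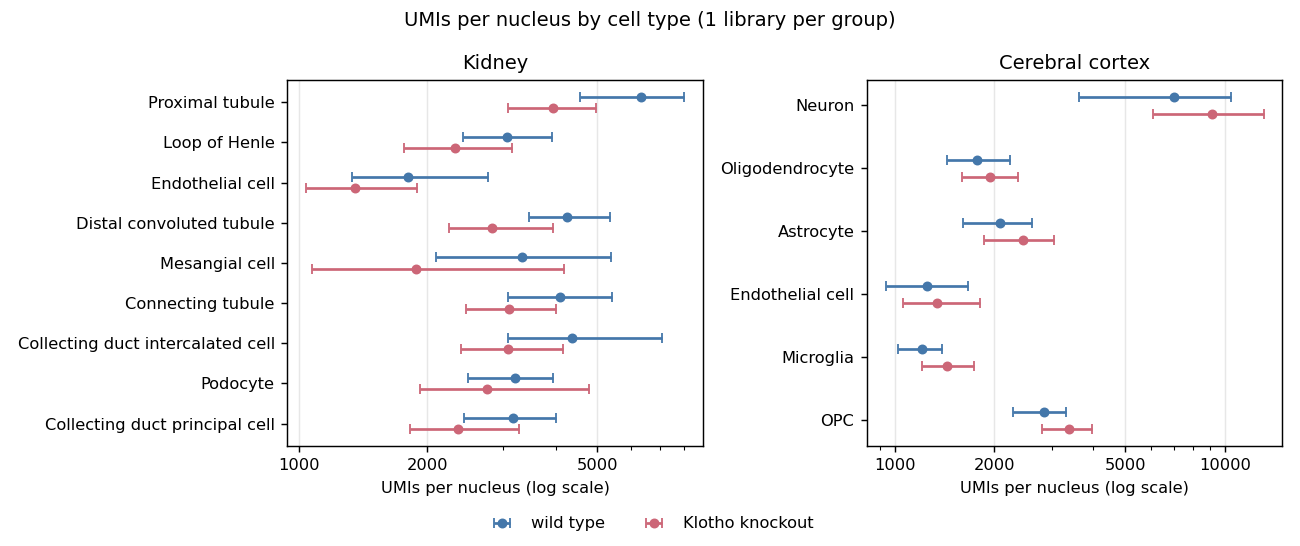
UMIs per nucleus (log axis) by annotated cell type in the kidney libraries (left) and the cortex libraries (right) for the wild-type (blue) and the Klotho knockout library (red); points are medians and bars run from the lower to the upper quartile of nuclei. The knockout median is the lower one in each of the 9 kidney types, for example 3948 against 6343 in proximal tubule, and the higher one in each of the 6 cortex types, for example 9146 against 7025 in neurons.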

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

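In this part the tests on podocytes, on the medians left after a loss at 500 UMIs, on the number of nuclei, on single factors and on the section were chosen after the shares and medians had been seen, and leaving out the proximal tubule and the log10 means were planned as alternatives but used as tests only then. Endothelial cells are the only type annotated in both tissues, and the ratio of their knockout to wild-type share was 0.46 in kidney, past the size rule, and 1.20 in cortex, which did not meet it. The difference between the tissues was not tested, since each rests on 1 library per genotype. UMIs per nucleus also went opposite ways, with a ratio of medians of 0.72 in kidney and 1.53 in cortex, as did detected genes per nucleus, with 0.81 in kidney and 1.36 in cortex. These pairs stood out because the ratio of median UMIs was below 1 in each of the 9 kidney types and above 1 in each of the 6 cortex types, and the difference was not tested.

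The lower share of endothelial and mesangial nuclei in the knockout kidney library was weighed first. Nuclei under 1000 UMIs were more frequent in the knockout, at 21.1% against 11.1% of endothelial and 23.0% against 7.46% of mesangial nuclei, as a loss of shallow nuclei needs. Wild-type nuclei thinned by the lowest depth ratio of any type and kept from 500 UMIs still held shares of 9.89% and 4.38%. Those shares lay above the knockout upper limits of 5.17% and 2.56%. The thinning decides little, because its factor comes from nuclei that all had at least 500 UMIs. It left 854 of 927 endothelial and 378 of 402 mesangial nuclei. If 1 depth factor per type had put the shortfall under 500 UMIs, the wild-type nuclei left would have median UMIs of 749 (interval 731 to 783) and 801 (741 to 850.0), where the knockout medians were 1350 (1247 to 1418) and 1885 (1625 to 2693). The tables thus argue against a loss through 1 depth factor per type as the whole cause. A loss that acts unevenly on the nuclei of a type was not addressed. A larger proximal tubule share does not account for the endothelial difference, since the ratio was 0.50 without those nuclei, which follows directly from the shares given above. Fewer glomeruli in the section would have lowered podocytes, whose ratio was 1.77. The annotation does not say which endothelial and mesangial nuclei were glomerular, so podocytes say little about nuclei of these types from outside glomeruli. A different section or an uneven recovery of nuclei cannot be told apart from genotype with 1 library per genotype, so a lower vascular and stromal content of the knockout kidney stays a hypothesis.

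The depth difference was weighed second. The tables argue against a difference in the mix of annotated types, because at the mean composition of both libraries the ratio of median UMIs was 0.70 in kidney and 1.52 in cortex. In cortex this step could change little, since neurons held 67.4% of the nuclei in both libraries. A shift within an annotated type, such as among kinds of neuron or parts of the proximal tubule, cannot be seen this way and was not addressed. Within single cortex types the ratios were smaller, at 1.07 to 1.30. In kidney the tables also argue against the same sequencing spread over more of the deposited nuclei, as the knockout library held 0.86 times as many. Read counts and the nuclei removed by filters are not given in the sources used here. Sequencing spent on removed nuclei was thus not addressed. A single factor for the whole kidney library would give every type the same ratio, but it was 0.62 in proximal tubule (interval 0.61 to 0.64) and 0.76 in loop of Henle (0.73 to 0.79), although the ratios of geometric means lay closer, at 0.74 and 0.79. The distal convoluted tubule interval (0.63 to 0.71) also lay below the loop of Henle interval. The intervals of endothelial, mesangial, connecting tubule, intercalated, principal and podocyte nuclei all held the loop of Henle ratio. Set beside the loop of Henle, the departure from a single factor thus lay in the proximal and distal convoluted tubules. Another reference type would place it elsewhere. The distal convoluted ratio of 0.67 lay within the intervals of endothelial, mesangial, connecting tubule, intercalated and principal nuclei. It lay below that of podocytes (0.73 to 1.13). The values thus do not settle which types depart from a single factor. In cortex the knockout library held 0.75 times the nuclei and 0.93 times the UMIs, but similar sequencing over fewer nuclei is also 1 factor, and the ratio was 1.30 in neurons (1.26 to 1.35) and lower in oligodendrocytes (1.05 to 1.15), so it does not account for the whole difference. The intervals of the cortex types other than neurons all overlapped each other, so among those types the ratios do not argue against 1 factor. RNA quality or capture that acts unevenly on types, and genotype itself, also stay open and untested.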

How the results depend on the processing

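The minimum of 1000 UMIs and the make-up of the broad classes were chosen after seeing the data; the other settings were not. Of the 4 kidney types called, endothelial, mesangial and podocyte kept their direction and stayed past the ratio of 1.5 under every setting run, with ratios of 0.36 to 0.50, 0.41 to 0.54 and 1.62 to 2.23. The ratio for endothelial nuclei moved most when the 10 UMI deciles had equal weight, to 0.36. The connecting tubule ratio lay between 0.45 and 0.55 except in broad classes, where it reversed to 1.09 because the class joins it with the distal convoluted tubule. Broad classes left 2 classes called in kidney, and 5 types were called without the proximal tubule. In cortex 0 types were called under each setting that allows intervals; with equal weight for UMI deciles the endothelial ratio was 1.53. Counts of called types were not made for shares of UMIs or weighted deciles, which have no binomial interval. With means of log10 values the ratio of UMIs was 0.78 in kidney and 1.28 in cortex, and that of genes 0.85 and 1.21; with at least 500 detected genes the cortex ratio of genes was 1.28. These ratios kept their direction, and the cause of the shifts with log10 means and with equally weighted deciles was not tested. The order of the kidney types by UMI ratio depends on the summary and on the filter: with log10 means the connecting tubule, among the 3 highest by medians, was at 0.73, below the proximal tubule at 0.74, which was among the 3 lowest, and with at least 500 detected genes mesangial cells, the lowest by medians of all nuclei, were at 0.67, above the proximal tubule at 0.61 and the distal convoluted tubule at 0.66. Of the other alternatives for uncalled types, 32 of 37 in kidney and 38 of 44 in cortex stayed within the counting interval. Ratios crossed 1 in 3 of those 37 and 9 of those 44: loop of Henle was at 0.93 with equally weighted deciles and proximal tubule at 0.99 by share of UMIs, and principal cells, joined with intercalated cells, at 1.02. In cortex, equally weighted deciles put microglia at 1.18, oligodendrocytes at 1.07, their precursors at 1.12 and neurons at 0.92, and astrocytes were at 0.98 by share of UMIs and in broad classes. Microglia with at least 1000 UMIs were at 1.01, and neurons at 0.99 there and in the shared UMI range. No alternative on mitochondrial percentages or deposited clusters was run, because the tables used here give none, and leaving out a replicate was not possible with 1 library per group. Some ratios rest on few nuclei, with 91 and 138 podocytes and 121 and 82 principal cells.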

Other observations

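The thinning of the wild-type kidney library was planned before its result was seen, broad classes were planned with their make-up set later, and the other tests and the UMI limits of this part were chosen after the shares and medians had been seen. Within cell types, the lower end of the UMI distribution did not always follow the median. Proximal tubule nuclei under 1000 UMIs were less frequent in the knockout kidney library, at 4.77% (215 nuclei, exact interval 4.17 to 5.44%) against 7.91% in wild type (394 nuclei, 7.17 to 8.69%), although the knockout median was lower. Mesangial nuclei under 1000 UMIs were more frequent in the knockout library, at 23.0% (40 nuclei, 17.0 to 29.96%) against 7.46% (30 nuclei, 5.09 to 10.5%), as were endothelial nuclei, at 21.1% (78 nuclei, 17.1 to 25.7%) against 11.1% (103 nuclei, 9.16 to 13.3%). Podocytes were the 1 kidney type whose upper quartile of UMIs was higher in the knockout, 4786 against 3945. In cortex, microglia with at least 2000 UMIs were 10.9% of knockout microglia (37 nuclei, 7.78 to 14.7%) and 2.37% of wild-type microglia (12 nuclei, 1.23 to 4.11%), beside a ratio of their medians of 1.20. Neurons under 2000 UMIs were 11.0% of knockout neurons (10.2 to 11.8%) and 17.2% of wild-type neurons (16.4 to 18.1%). There were 1.07 microglial nuclei per endothelial nucleus in wild-type cortex (0.94 to 1.22) and 0.80 in the knockout (0.69 to 0.93).

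The connecting tubule was examined as a hypothesis formed after its values were seen, that nuclei of this segment in the knockout kidney may have been named distal convoluted tubule. That needs the sum of both segments to keep its share, and the ratio of the summed shares was 1.09 with overlapping intervals, so the values it needs are there. A loss of shallow nuclei was also weighed. The thinned wild-type library still had a connecting tubule share of 3.44%, above the knockout upper limit of 2.01%, but this decides little, since 297 of 302 nuclei were left. If 1 depth factor had put the shortfall under 500 UMIs, the nuclei left would have a median of 677 UMIs (643 to 738). The knockout median was 3105 (2884 to 3388), which argues against a loss through 1 depth factor. A loss that acts unevenly on these nuclei was not addressed. A difference between the genotypes in the cells of the 2 segments stays open and untested, and marker genes per nucleus would be needed to decide.

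At matched UMIs, in bins of 0.1 on the log10 scale with at least 30 nuclei per library, proximal tubule nuclei of the knockout had 1.02 times as many detected genes as wild type, with a range over 17 bins of 0.98 to 1.11. Loop of Henle nuclei had 0.96 times as many over 8 bins, neurons 1.03 times over 20 bins and microglia 1.04 times over 3 bins. Barcodes present in both of 2 libraries numbered between 113 for the kidney pair and 172 for the cortex pair, and pairs of libraries from different tissues shared 121 to 160. Over the 6 pairs of libraries this was 1.43 to 1.84% of the barcodes of the smaller library.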
